A study of Mus musculus with 6 samples.

How the data were processed

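Lumbar dorsal root ganglia, which hold the cell bodies of the sensory neurons of the trunk and hindlimb, were dissected from mouse embryos at E12.5. RNA was extracted with Trizol, and stranded libraries were made from polyadenylated RNA, per the labels' protocols. The labels give 3 control and 3 miR_cKO mice on a mixed strain background. In miR_cKO, the floxed cluster of miR-183, miR-96 and miR-182 was deleted with Wnt1-Cre, which acts in the neural crest and so in sensory neurons and their glia. Controls 1 and 3 carried the Cre, and control 2 was titled wild type. All 6 libraries share 1 run and lane in the labels, so no sequencing batch parts them. Whether a library pooled several embryos is not given in the sources used here.

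Reads were aligned with Bowtie to mm10, per the submitters' processing notes, with no version given there. The counting tool, the annotation and the handling of reads shared between loci are not given in the sources used here. The authors deposited 1 table with 24264 genes and 1 column for each library. Its header names no unit. Its values were read as RPKM, reads per kilobase and per M mapped reads (M, mega), because the deposited values of a gene were whole multiples of a step that fell with transcript length (Spearman rho -0.897 across 1669 genes with 1 annotated transcript, which are not independent replicates). RPKM and FPKM cannot be told apart from the values. Numbers are written with a decimal comma in the table. No column of values per sample was left unused.

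Depth was estimated from these steps. Whole reads, within 0.01 read, were found for 88.6% of the genes above 0 in at least 2 libraries. They were found for 83.5% of the 13118 genes tested. The estimated depth was 21.4, 24.0 and 19.9 M reads in controls 1 to 3 and 22.2, 21.9 and 20.6 M reads in miR_cKO 1 to 3. In the tested genes with whole reads, the median was 511 reads per library. The libraries of a group differed by more than counting noise, with a chi-square per gene between 10.0 and 23.4, so each was kept as a replicate. Genes with near-identical copies, such as haemoglobin and mitochondrial genes, are uncertain because reads between copies may have been split.

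The tests, gene lists and rule for named genes were fixed before the data were examined. Values were transformed to log2(RPKM + 1), and genes were kept where at least 3 libraries had 1 RPKM or more. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with trend and robust settings) with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. On simulated data with these 13118 genes, 89.4% of planted log2 changes of 1 and 41.6% of those of 0.5 were found. The genes were drawn as independent, with 100 changed at each size, so these shares leave out differences that many genes share between libraries. Of the simulated calls 5.76% were false. The planned test for a count table was not used, since the table holds no counts.

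Of 26 gene lists fixed, 21 had the 5 tested genes needed. Lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 21 lists. Camera with an estimated correlation and fry stood beside it. Lists covered sensory neurons and their classes, glia, neurogenesis, synaptic vesicle and channel genes, cell cycle, stress and early response genes, Hox genes, mitochondrial genes, published targets of the cluster, and markers of muscle, mesenchyme, cartilage, endothelium, macrophages, red cells, sympathetic neurons and spinal cord.

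Seed sites were searched in the 3 prime UTR of the main transcript of each gene in GENCODE M21, which uses mm10. Of the table's names, 20883 were symbols there and 1720 were matched through a RefSeq synonym. An annotated 3 prime UTR was found for 19675 genes, and 12114 of the tested genes had one. Sites were 8mer and 7mer matches to the seeds of miR-183, miR-96 and miR-182. The shift is the median log2 change of genes with a site minus that of genes without one, matched on UTR length and mean level. In 10 simulations of independent genes without a planted shift none had a camera p under 0.05, and a planted shift of 0.1 was recovered as 0.0988. The correlation estimated for genes with a site was 0.0248, so these simulations do not show how camera behaves with correlated genes. All 7-mers present in at least 100 genes were also ranked by a rank-sum z, with SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15. A planted shift of 0.05 put the planted 7-mer at rank 1 in each of 5 simulations. Figures were drawn with matplotlib 3.10.9.

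The rule for named genes takes the deleted genes, Wnt1 and the sex-linked genes. It then takes up to 10 genes each way past the threshold with separate groups, filled up with the smallest p where fewer passed. It adds the 4 members with the smallest p of each list that passed and of 6 lists fixed in advance, and up to 5 higher genes with the most seed sites. Genes with Gm or Rik symbols and pseudogenes were skipped among the up to 10 genes each way. A comparison of 3 with 3 libraries by exact permutation cannot go below p = 0.1. Alternatives covered the scaling, filter, pseudocount, test, threshold, replicate number as a block, each library left out, site definition and list test.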

Results

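Gene expression was measured by RNA sequencing in lumbar dorsal root ganglia of E12.5 mouse embryos. There were 3 control and 3 miR_cKO libraries, the latter with the cluster of miR-183, miR-96 and miR-182 deleted in the neural crest lineage. The cluster encodes 3 microRNAs with related seeds that are expressed together in sensory neurons. The comparison asks which messages change when these microRNAs are lost. The estimated depth was 19.9 to 24.0 M reads per library.

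The deleted genes could not check the labels. Mir183 (mm10 chromosome 6, 30169668 to 30169737, minus strand), Mir96 (30169446 to 30169551) and Mir182 (30165918 to 30165992) were listed at 0 in all 6 libraries. Poly(A) libraries hold few microRNA precursors, so these values check nothing. Wnt1, whose promoter drives the Cre, was at 1.38, 0.261 and 0.147 RPKM in controls 1 to 3 and at 0.319, 1.88 and 4.56 RPKM in miR_cKO 1 to 3. This difference of 0.87 on the log2 scale was within the spread (two-sided exact permutation p = 0.2, smallest possible 0.1), and was 0.37 without miR_cKO 3 and 1.41 without miR_cKO 1. By sex-linked genes, miR_cKO 1 stood apart. Xist, the RNA of the inactive X chromosome, was at 96.0 RPKM there and at no more than 0.0890 RPKM elsewhere. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 0.0416 RPKM or less in miR_cKO 1 and at 5.74 RPKM or more in each of the 5 other libraries. The labels give no sex.

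Of 13118 genes tested, 7 were higher and 1 was lower in miR_cKO (limma, Benjamini-Hochberg adjusted p under 0.05). Nova2, a neuronal RNA-binding protein that regulates splicing, rose from 4.86 ± 0.175 to 18.6 ± 3.65 RPKM (SD, n = 3 each), a log2 change of 1.72 (SE 0.14, limma adjusted p = 0.0428). Onecut3, a homeodomain transcription factor, rose from 1.69 ± 0.425 to 6.81 ± 0.874 RPKM. Vat1, a vesicle-associated membrane protein, rose from 19.5 ± 1.91 to 56.1 ± 9.03 RPKM. Slc25a1, the mitochondrial citrate carrier, rose by 0.86 on the log2 scale, Atp1b3, a beta subunit of the sodium-potassium ATPase, by 0.65, and Arf2, a small GTPase of membrane traffic, by 0.64. The remaining higher gene was 4930402H24Rik, annotated as protein-coding, at 18.8 ± 0.595 and 32.0 ± 2.50 RPKM. Its Rik symbol put it outside the naming rule, and it was named after its values were seen. Stx2, a syntaxin of membrane fusion, fell from 29.1 ± 4.09 to 12.1 ± 0.891 RPKM, a log2 change of -1.19 (SE 0.11, limma adjusted p = 0.0428).

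**Figure D1:**
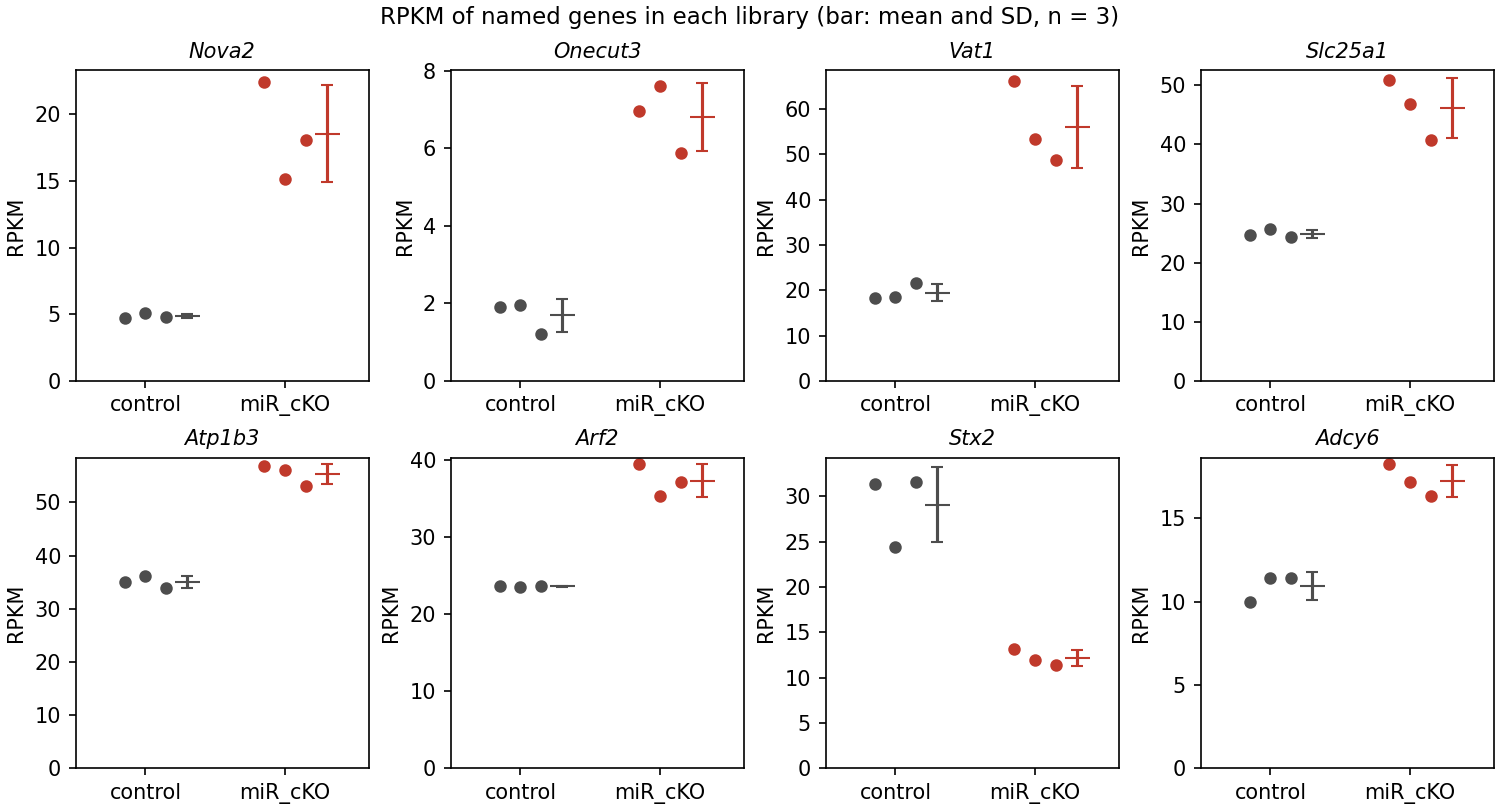
RPKM of the 6 named higher genes, Stx2 and Adcy6 in each of 3 control (grey) and 3 miR_cKO (red) libraries, with a bar for mean and SD. In each of the 8 panels the groups do not overlap; Stx2 alone is lower in miR_cKO.

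The higher genes next in order did not pass. Resp18, a neuroendocrine secretory protein, was at 9.55 and 17.4 RPKM, and B4galnt1, an enzyme of ganglioside synthesis, at 2.41 and 6.05 RPKM. Ostm1 and Tmem68 had log2 changes of 0.67 and 0.58 (limma adjusted p = 0.0881 for each of these 4 genes). Among lower genes that did not pass, Spp1, which encodes the secreted protein osteopontin, was at 1.63 and 0.438 RPKM (limma adjusted p = 0.107). The small heat shock gene Hspb8 had a log2 change of -0.88, Cpne3 of -0.62, Myo6 of -0.57 and the ETS factor Etv5 of -0.48. H2-DMa, Gng8, Atg4a and Kcnab1 had log2 changes of -0.97, -1.20, -0.53 and -0.57. The groups did not overlap for 1426 genes, 10.9% of those tested, where chance gives 10%; 607 of them were higher and 819 lower. Of all genes 40.4% had a log2 change above 0, and 52.1% with median centring. At an unadjusted p under 0.05 there were 374 higher and 303 lower genes.

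The count of changed genes depended on the processing: limma with upper quartile scaling, scaling without haemoglobin and mitochondrial genes, or no trend gave 0, beside 698, 681 and 705 genes at an unadjusted p under 0.05, and median centring gave 2. In these fits the highest limma adjusted p of the 8 genes was 0.0661, 0.0708, 0.0963 and 0.0576. With a replicate left out it reached 0.369. Without control 1, 2 or 3 limma called 1, 1 and 0 genes. It called 2, 0 and 0 without miR_cKO 1, 2 or 3, with 440 to 1023 genes at an unadjusted p under 0.05 in these fits. All 8 genes kept their sign, which was fixed in advance, as their groups did not overlap with all libraries in. The gene called without control 1 was none of the 8, and the 9 genes called without the filter (6 higher, 3 lower) shared 3 with them.

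Messages with seed sites of the deleted microRNAs were shifted upward in miR_cKO. The 4069 genes with a site in the 3 prime UTR had a median log2 change 0.0326 above that of matched genes without one (camera, adjusted p = 2.33e-06). The adjusted p was 0.0497 with an estimated correlation. A separate measure, taken within each library as a median deviation from the mean of all libraries, does not add up to the fitted shift. It was -0.0249 ± 0.00514 in controls and 0.0241 ± 0.0104 in miR_cKO (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). This measure was negative in 3 of 3 controls and positive in 3 of 3 miR_cKO libraries. By microRNA, the shift was 0.0466 for miR-96, 0.0391 for miR-182 and 0.0293 for miR-183, with adjusted p = 0.0334, 0.0334 and 0.0509 with an estimated correlation. These sets overlap, and for genes with miR-183 sites alone the shift was 0.0181, with an adjusted p = 0.214 with an estimated correlation. Fry, a rotation test that asks only whether site genes move on balance in a single direction, gave an adjusted p = 0.478 for any site.

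**Figure D2:**
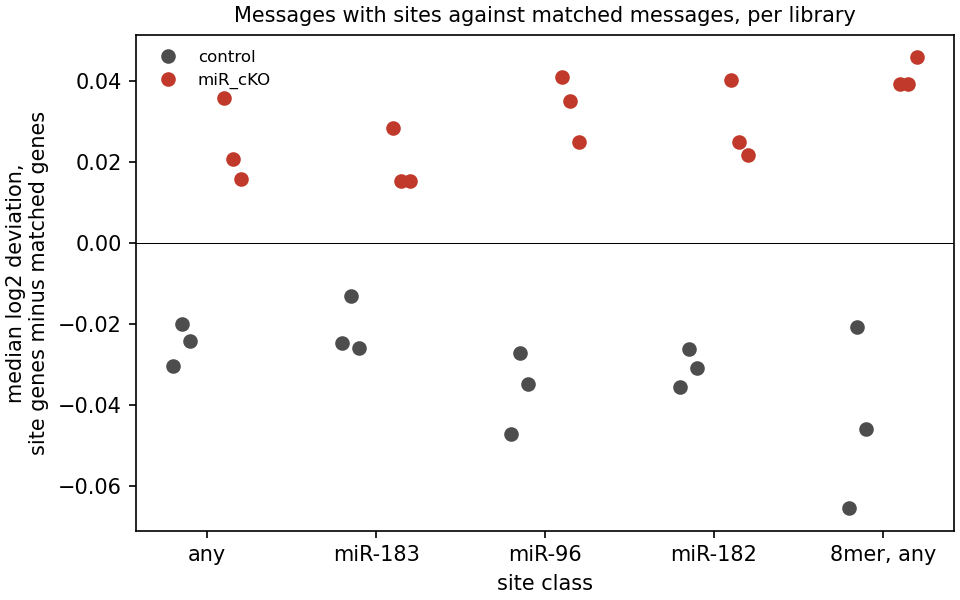
Median log2 deviation of messages with a site minus matched messages without one (y axis), for 5 site classes (x axis), in 3 control (grey) and 3 miR_cKO (red) libraries. Each control point lies below 0 and each miR_cKO point above 0.

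Median changes were higher with more sites, a trend given as values without a test. These medians are not matched on UTR length or level, so the trend is not one of site number alone. For genes with 2 or more sites, matching moved the median of genes without a site from -0.0363 to -0.0246, and the matched shift was 0.0494. The median log2 change was -0.036 in 8045 genes with 0 sites, -0.0069 in 2630 genes with 1, 0.022 in 939 genes with 2 and 0.033 in 500 genes with 3 or more. With 8mer sites alone the matched shift was 0.0618. In 133 genes with 2 or more 8mer sites the median log2 change was 0.13. Among 15677 ranked 7-mers, those of the cluster held ranks 1 to 4. TGCCAAA, shared by miR-96 and miR-182, ranked 1 (z 18.4), GTGCCAA of miR-96 ranked 2 (z 18.1), TTGCCAA of miR-182 ranked 3 (z 11.5) and GTGCCAT of miR-183 ranked 4 (z 10.9). The remaining site, TGCCATA of miR-183, ranked 759. GCCAAAA and TTTTAAA, which are no cluster sites, ranked 5 and 6 (z 10.9 each). Only ranks 1 and 2 thus stood well clear of other 7-mers. These ranks are across genes, which are not independent replicates.

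**Figure D3:**
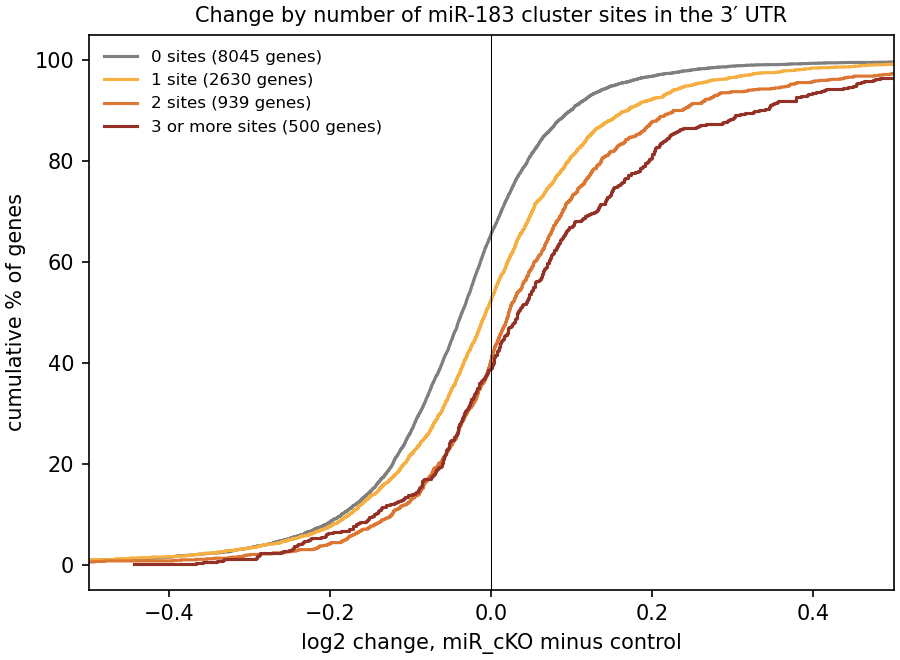
Cumulative percentage of genes (y axis) by log2 change in miR_cKO against control (x axis, shown from -0.5 to 0.5), for genes with 0, 1, 2 and 3 or more cluster sites in the 3 prime UTR. Medians run from -0.036 with 0 sites to 0.033 with 3 or more, without matching on UTR length or level.

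All 7 genes that rose carried a site, against 33.6% of the other genes with a 3 prime UTR (Fisher's exact test, p = 0.000481). Of 337 genes that were higher at an unadjusted p under 0.05 and had a 3 prime UTR, 81.0% carried a site, as did 24.5% of the 249 lower ones. These shares were not matched on UTR length or level. The Nova2 UTR on chromosome 7 holds 4 copies of the miR-96 8mer GTGCCAAA, at 18960918 to 18960925, 18961873 to 18961880, 18962279 to 18962286 and 18965265 to 18965272 (mm10, plus strand). It also holds a miR-182 7mer at 18965134 to 18965140. Arf2 has this 8mer at 103984151 to 103984158 and at 103984369 to 103984376 on chromosome 11, plus strand. Vat1 has miR-96 and shared 7mers at 101459851 to 101459857 and 101459334 to 101459340 on chromosome 11, minus strand. Atp1b3 has the miR-182 8mer TTGCCAAA at 96333237 to 96333244 on chromosome 9, minus strand. Onecut3 has it at 80515084 to 80515091 on chromosome 10, plus strand. Stx2, which fell, carries 1 miR-183 7mer at 128984880 to 128984886 on chromosome 5, minus strand.

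Published targets of the cluster, were higher as a set. Of 15 tested members, 11 were higher and 4 lower, with a mean log2 change of 0.17 (camera, adjusted p = 3.96e-07). The adjusted p was 0.190 with an estimated correlation, 0.10 by fry for a single direction and 0.00775 by fry for change in either direction. No member passed over all genes, and 1 passed adjusted over the list alone. This was Adcy6, an adenylyl cyclase with 6 sites, which went from 10.9 ± 0.821 to 17.3 ± 0.949 RPKM (limma, adjusted p = 0.00198 when adjusted over the list alone). The actin-linked genes Ezr and Cttn and the transcription factor Shox2 had log2 changes of 0.30, 0.21 and 0.43. Whether the study picked any member from these libraries is not given in the sources used here, so the list is not taken as independent evidence of its direction.

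Sensory neuron classes gave no directional call in the planned camera test. In the proprioceptor list, the genes of muscle-sensing neurons, 0 of 10 members passed over all genes and 3 passed adjusted over the list alone. Spp1 (limma, adjusted p = 0.00228) and the ETS factor Etv1 (adjusted p = 0.0155) fell by that criterion, with Etv1 at 8.83 and 5.26 RPKM, and the cadherin Cdh13 rose (adjusted p = 0.0155), at 3.21 and 5.08 RPKM. Fry for change in either direction gave an adjusted p of 0.0344 for this list, and camera gave 0.898. Its member Ntrk3, the neurotrophin-3 receptor, had a log2 change of 0.21. The low-threshold mechanoreceptor list had 10 of 15 members lower (camera adjusted p = 0.392), with Etv4 at a log2 change of -0.39. The nociceptor list, for pain-sensing neurons, had 12 of 13 members lower and a mean of -0.23 (camera adjusted p = 0.151). Single libraries decided this list: it passed without control 2 (mean -0.46, adjusted p = 0.000696) and without miR_cKO 1 (-0.45, adjusted p = 0.00103), and its mean was -0.065 without control 3 and without miR_cKO 2. With all 6 libraries it passed with a replicate block (-0.23, camera adjusted p = 0.0386) and with array weights (-0.49, adjusted p = 0.000938). It also passed with the muscle list as covariate (-0.49, adjusted p = 0.00130). Its adjusted p in the planned fit was 0.923 with an estimated correlation. Its Tac1, Ptgir, Prdm12 and Scn10a had log2 changes of -0.68, -0.44, -0.32 and -0.71. The general sensory neuron list was near 0 (camera adjusted p = 0.498), and its mean of -0.0053 and median of -0.033 were below 0 while the test's direction was up. It passed without control 1 (mean 0.057, adjusted p = 0.0468) and without miR_cKO 3 (0.13, adjusted p = 0.000167), and its mean was -0.12 without control 2 and -0.14 without miR_cKO 1. The adjusted p of the planned fit was 0.923 with an estimated correlation. Gap43, Stmn2, Elavl4 and Pou4f1 had log2 changes of 0.39, 0.22, 0.12 and 0.088. Glial and Schwann cell precursor genes had a mean log2 change of 0.021 and a median of -0.0024, with a test direction of up (camera adjusted p = 0.665); they passed without miR_cKO 3 (mean 0.064, adjusted p = 0.00619), and the adjusted p of the planned fit was 0.923 with an estimated correlation. Prss56, Mbp, Pmp22 and Tfap2a had changes of 0.30, -0.32, -0.24 and 0.30.

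Among markers of other tissues, muscle and mesenchyme lists were lower in miR_cKO. Muscle genes had a mean log2 change of -1.33, with 8 of 9 lower (camera adjusted p = 0.000496), and mesenchyme genes one of -0.38, with 18 of 18 lower (camera adjusted p = 0.000119). Both had an adjusted p of 0.923 with an estimated correlation. The difference lay in controls 2 and 3. Cardiac actin, Actc1, was at 2.33, 56.3 and 41.2 RPKM in controls 1 to 3 and at 1.31, 2.27 and 6.09 RPKM in miR_cKO 1 to 3. Tnnt1, Myl4 and Myh3, which encode muscle filament proteins, had log2 changes of -1.64, -1.49 and -1.84 with none past the threshold. In the mesenchyme list, Col3a1 was at 115 ± 27.3 and 85.2 ± 13.6 RPKM, and Tbx18, Foxc2 and Lum had changes of -0.32, -0.37 and -0.30. With controls 2 and 3 left out, the means turned to 0.18 for the 5 muscle genes still tested and 0.11 for the 17 mesenchyme genes. These means rest on 1 control and on fewer genes than the main fit. Without control 2 alone, muscle did not pass (mean -0.60, camera adjusted p = 0.244). The muscle mean was -2.10 without control 1 and -0.87 without control 3, and the mesenchyme mean was -0.63 without control 1, -0.23 without control 3 and -0.23 without miR_cKO 1, all past the threshold.

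Another 4 lists passed with the preset correlation, none of them with an estimated one (adjusted p = 0.923 each). Mitochondrially encoded genes were higher in 13 of 13 members, with a mean log2 change of 0.18 (camera adjusted p = 0.00279). The complex I genes mt-Nd3, mt-Nd4, mt-Nd6 and mt-Nd4l had changes of 0.15, 0.25, 0.44 and 0.25. The list did not pass without control 2 (mean 0.15, adjusted p = 0.0701), control 3 (0.064, adjusted p = 0.302) or miR_cKO 1 (0.11, adjusted p = 0.164), and its mean was 0.31 without control 1. Cell cycle genes were higher in 24 of 25 members with a mean of 0.092 (camera adjusted p = 0.0317), and Mki67, Mcm7, Ccne1 and Pcna had changes of 0.17, 0.18, -0.16 and 0.13. Their mean was 0.0089 without control 1, 0.0095 without control 3, 0.020 without miR_cKO 2 and -0.043 without miR_cKO 3, none of which passed, and 0.26 and 0.30 without control 2 and without miR_cKO 1. Hox genes were higher in 16 of 22 members with a mean of 0.15 (camera adjusted p = 0.0209). Hoxb9, Hoxb8, Hoxd8 and Hoxc6 had changes of 0.67, 0.52, 0.21 and 0.44, and the list mean was -0.13 without miR_cKO 3; the list did not pass without control 1 or control 3 either (adjusted p = 0.221 and 0.0645). Synaptic vesicle genes were higher in 15 of 22 members with a mean of 0.083 (camera adjusted p = 0.0320), which was -0.044 without control 2 and -0.068 without miR_cKO 1. Within this list Rab3c, a vesicle GTPase with 4 sites, passed adjusted over the list alone (limma, adjusted p = 0.0371, 7.30 and 13.4 RPKM), while Slc17a7, Syt1 and Sv2a had changes of 0.49, 0.26 and 0.25. The list did not pass with upper quartile scaling (camera adjusted p = 0.0562), scaling without haemoglobin and mitochondrial genes (0.0561) or a minimum of 10 RPKM (0.215). With median centring, synaptic vesicle, cell cycle and Hox genes did not pass (camera adjusted p = 0.0857, 0.0790 and 0.0780).

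**Figure D4:**
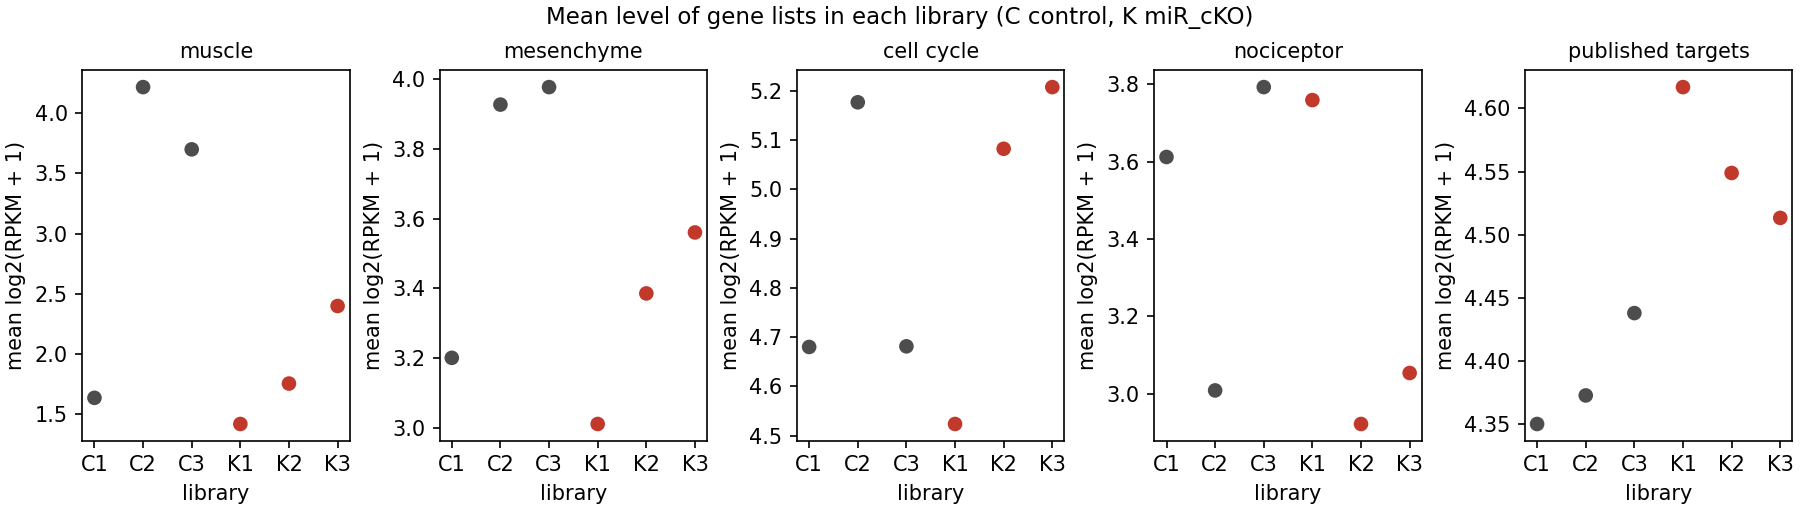
Mean log2(RPKM + 1) of 5 gene lists (y axis, a range of its own in each panel) in each library (x axis, C control in grey, K miR_cKO in red). Muscle is highest in controls 2 and 3, cell cycle and nociceptor levels part control 1, control 3 and miR_cKO 1 from the rest, and published targets are higher in all 3 miR_cKO libraries.

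The remaining lists did not pass the planned camera test. Mean log2 changes were -0.33 for cartilage, 0.046 for endothelium, 0.15 for red cells, -0.095 for macrophages, -0.16 for sympathetic neurons, 0.17 for sensory neurogenesis, 0.014 for voltage-gated channels (median -0.014, test direction up), -0.027 for cell death and stress and -0.017 for immediate early genes. Immediate early genes had a median of 0.0071 and a test direction of up. Single libraries decided several of these lists at the preset correlation, and each list had an adjusted p of 0.923 with an estimated correlation in the planned fit. Cartilage passed without control 1 (mean -0.75, adjusted p = 0.000231) and without miR_cKO 3 (-0.60, adjusted p = 0.0133). Its mean was -0.13 without control 2, -0.11 without control 3 and -0.11 without miR_cKO 1, none of which passed. Red cell genes passed upward without control 1 (0.53, adjusted p = 0.00117) and downward without control 3 (-0.36, adjusted p = 0.0151). Sensory neurogenesis genes passed without control 2 (0.35, adjusted p = 4.41e-05) and without miR_cKO 1 (0.29, adjusted p = 0.0191). Their mean was 0.034 without control 3 and 0.043 without miR_cKO 3, neither of which passed. Endothelial genes passed without miR_cKO 1 (0.16, adjusted p = 0.00222) and without miR_cKO 3 (0.074, adjusted p = 0.0305), and their mean was -0.093 without miR_cKO 2 and -0.023 without control 1. Voltage-gated channels passed without control 3 (0.12), miR_cKO 2 (0.081) and miR_cKO 3 (0.087), with adjusted p = 0.0123, 0.0251 and 0.00295, and their mean was -0.092 without control 2 and -0.11 without miR_cKO 1. Means of the opposite sign were also found for macrophages (0.12 without miR_cKO 1 and 0.014 without control 2) and immediate early genes (0.071 without control 2 and 0.047 without miR_cKO 1). With a library left out, the sympathetic mean ran from -0.31 without control 2 to -0.029 without control 3, and this list never passed. Histone and spinal cord lists had too few tested members. The mean log2 levels of the 24 spinal cord genes were 0.238, 0.453 and 0.524 in controls 1 to 3 and 0.446, 0.188 and 0.916 in miR_cKO 1 to 3. Those of the 17 histone genes lay between 0.562 and 0.802.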

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

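The covariates, fits with several libraries left out, voom, array weights, the UTR trend, sites of 1 family, and the further scalings and pseudocount of the seed shift were chosen only after the data were seen. The number of changed genes was 0 with limma under upper quartile scaling, scaling without haemoglobin and mitochondrial genes, no trend, the muscle list as covariate, 2 against 2 libraries (without control 2 and miR_cKO 3), 1 against 3 (without controls 2 and 3, the lone control assumed to vary like the rest) and voom on recovered reads, beside 698, 681, 705, 803, 478, 395 and 650 genes at an unadjusted p under 0.05. It was 9 without the filter, sharing 3 of the 8 main calls, 2 with median centring, 25 at a threshold of 0.1, 34 with array weights and 76 with the cell cycle list as covariate; the fits with 34 and 76 share all 8 main calls. With a replicate left out it was 0 to 2, from fewer samples. The called genes kept their sign in each fit that tested them. Where libraries were left out this was fixed in advance, as the groups of these genes did not overlap. Replicate numbers did not pair the samples, as same-number correlations were 0.359, 0.330 and -0.221 and not every sample correlated best with its own number; a replicate block gave 0 genes (847 at an unadjusted p under 0.05), 9 lists, with cartilage and nociceptor genes gained (adjusted p = 0.0107 and 0.0386), and a seed shift of 0.0326. Of 21 lists tested, 7 passed, 4 with median centring, 0 with an estimated correlation and 0 with fry for a single direction; 2 passed fry for either direction. With a replicate left out 6 to 10 passed, 4 to 6 of them among the 7. Published targets did not pass with an estimated correlation (adjusted p = 0.190) or fry (0.10), which leave the mean at 0.17 by construction, and had means of 0.14 to 0.20, all past the threshold, with a replicate left out. The seed shift was above 0 in the 22 alternatives that moved it, and 4 others (median centring, block, estimated correlation, fry) leave it at 0.0326 by construction. It ran from 0.0181 for miR-183 sites alone to 0.0618 for 8mer sites. It was 0.0365 to 0.0408 with a replicate left out, each above 0.0326, for which the cause was not tested. Genes with a site did not pass with fry (adjusted p = 0.478), which asks about their change alone and not about the shift. With a replicate left out, means ran from -0.068 to 0.19 for synaptic vesicle genes (-0.044 without control 2), from -0.13 to 0.38 for Hox genes, from -0.043 to 0.30 for cell cycle genes and from -0.36 to 0.53 for red cell genes. With the muscle covariate they were 0.44 for cartilage, -0.21 for general sensory neuron and -0.10 for synaptic vesicle genes (camera adjusted p = 0.00444, 0.00130 and 0.0403). They were 0.060 for mesenchyme and -0.036 for mitochondrial genes in that fit, neither of which passed. With 1 against 3 they were 0.50 for cartilage, -0.59 for red cells, 0.11 for mesenchyme, 0.18 for muscle, -0.097 for mitochondrial, -0.13 for general sensory neuron and -0.024 for synaptic vesicle genes. Array weights gained nociceptor, endothelial, red cell and sensory neurogenesis genes (adjusted p = 0.000938, 9.40e-05, 0.0148 and 0.00191), and the muscle covariate gained low-threshold mechanoreceptor genes among others (0.0403). The Hox mean was -0.029 with 2 against 2, and the synaptic vesicle mean -0.0080 with array weights. The cause of these reversals was not tested. In simulations of independent genes at this n, 41.6% of log2 changes of 0.5 were found.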

Other observations

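The tests on other splits, muscle RNA and the size of the shift along the library axis were chosen after the result was seen. So were those of ganglion stage, depth, sex and chromosomes, and the cut-off that read the 7-mer ranking as loss of the microRNAs. The ranking itself was planned. The libraries differed along an axis that did not follow genotype. The first principal component held 42.7% of the variance. Control 1, control 3 and miR_cKO 1 lay on one side of it, at -12.2, -4.39 and -22.0, and the nearest of the rest, miR_cKO 2, lay at 3.72. Parting these 3 libraries from the rest gave 599 genes past the threshold, 308 higher and 291 lower in them, against 8 for the real groups. This split was taken as the one of 10 with the most genes, so a count no lower than that of the real groups was fixed by the choice. Among the 291 were 24 of the 25 cell cycle genes, and among the 308 were 7 nociceptor genes. The nociceptor list had mean log2 levels of 3.61, 3.79 and 3.76 in control 1, control 3 and miR_cKO 1, and of 3.01, 2.92 and 3.05 in control 2, miR_cKO 2 and miR_cKO 3. Scn10a, a sodium channel of pain-sensing neurons, was at 22.8, 27.7 and 22.1 RPKM in the first 3 and at 8.72, 7.45 and 6.72 RPKM in the rest.

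A candidate explanation of this axis is the stage of the ganglia at dissection. Cell cycle and sensory neurogenesis lists were lower and the nociceptor list higher in each of the 3 libraries than in each of the rest, so 3 of 3 lists lay on the side that a later stage needs, but these levels are what prompted the question and so leave stage open. Depth does not part the libraries, since the 3 reached 22.2 M reads and the rest lay between 20.6 and 24.0 M. Embryo sex does not either, as 2 of the 3 libraries expressed Eif2s3y and miR_cKO 1 did not. By the titles, controls 1 and 3 carried Cre and control 2 was wild type. The titles of miR_cKO 1 to 3 name no Cre, which is taken from the knockout design. That design puts Cre in miR_cKO 1 to 3 alike, so Cre alone does not part the libraries along the axis. Among these carriers, miR_cKO 1 lay with controls 1 and 3, and miR_cKO 2 and 3 lay with control 2. A lesser part of Cre in the axis was not tested.

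For the upward shift of messages with seed sites, base composition and length of the UTR are argued against as the whole cause. With the trend on both removed, 4 of the 5 7-mer sites stayed among the first 10. The z fell from 18.4 to 14.0 for TGCCAAA, 18.1 to 15.1 for GTGCCAA, 11.5 to 7.12 for TTGCCAA and 10.9 to 7.19 for GTGCCAT. For TGCCATA it fell from 6.19 to 2.19. A rank does not show these falls, so a part of length and composition is left open. A test written in advance for the library axis looked for the sites' best rank along that axis, which was 10 and so on the side of that explanation, but it decides nothing because each other split still holds 33.3% of any genotype difference. By size, the shift along the axis was 0.00737 against 0.0326 by genotype, which argues against the axis as the whole cause. Loss of the deleted microRNAs needs their sites at the top of the ranking, and 4 of the first 5 7-mers were theirs. A site also held rank 1 at either end in 3 of the 9 other splits, and in 8 of the 9 with the trend removed. As each of these splits holds 33.3% of any genotype difference, this counts neither for nor against the loss. The ranking was planned, but the cut-off for reading it as the loss was chosen after the result was seen. The loss may thus be held only as a hypothesis.

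The libraries can be split in 10 ways, too few for a share under 0.05. The real split gave a seed shift of 0.0326, and the highest other one was 0.0241, so 1 split was as large, itself. Camera at the preset correlation gave an unadjusted p of 1.75e-06 for the real split and of 0.000171 to 0.845 for the others. Each of those still holds 33.3% of any genotype difference. For the published targets the mean was 0.17 and the highest other 0.12, again with 1 split as large. For changed genes the real count was 8 and the highest other 599, with 2 splits as large, which points to the structure of the samples described above. For gene lists 7 passed, the highest other was 13, and 9 splits gave as many.

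Lower muscle messages in miR_cKO are a candidate for tissue RNA carried along at dissection in controls 2 and 3. Of the 9 tested muscle genes, 8 had both of these controls above the 4 other libraries. This restates the levels that prompted the question, so it leaves such RNA open. The exception, Pax3, is also a neural crest gene. An effect of genotype stays open too. With controls 2 and 3 left out the mean change of the 5 genes still tested, Pax3 among them, was 0.18. This rests on 1 control, which gives no spread to set it against.

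Within 20 Mb of the deleted locus on chromosome 6, 11 of 148 genes had an unadjusted p under 0.05, an odds ratio of 1.56 against the other genes (0.756 to 2.90, Fisher's exact test p = 0.176), and 0 of the 8 called genes lay there. Stx2, Spp1 and Hspb8 lie on chromosome 5, from 128984557, 104435118 and 116408491. Lower genes had an odds ratio of 1.43 on this chromosome (Fisher's exact test p = 0.123, adjusted p = 0.904). The smallest adjusted p of any chromosome was 0.263, for chromosome 17. A count over a whole chromosome cannot exclude a shorter linked stretch, so linkage of these genes is left open.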
